A study of Brassica oleracea with 7 samples.

How the data were processed

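Poly(A)+ RNA from 7 tissues of Brassica oleracea was sequenced, with 1 library per tissue. Per the labels' protocols, flower bud, open flower, silique, leaf, stem and root came from greenhouse plants kept at 15 to 25 °C, and callus was grown in tissue culture at 25 °C. Each library started from 20 µg of total RNA. The cDNA was nebulised, fragments of 200 ± 20 bp were selected on a gel, 15 cycles of PCR were run, and the libraries were sequenced as paired ends on a HiSeq 2000. The labels' protocols name no step that marks strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart.

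The deposited table gives FPKM, that is fragments per kilobase of gene model scaled to the mapped fragments of the library, for 39481 genes in each tissue, per the file headers. It also gives a lower and an upper bound for each FPKM, as deposited by the authors. TopHat 1.0.13 is named in the submitters' processing notes. The column layout is that of the gene tracking table written by Cufflinks, but the program, its version, the genome build and the annotation are not given in the sources used here. Coordinates are therefore those of the deposited table, on its own scaffolds, with starts raised by 1 so that they count from 1. The files do not pair the gene IDs with gene names. Of the IDs, 0 matched the RefSeq gene table supplied for the species (assembly BOL, 53125 genes), so genes are given by ID. The 15 gene lists fixed before the data were examined therefore had 0 members, and no value was computed for them.

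The width of the deposited intervals gave the number of fragments behind each value. The distance from FPKM to the upper bound was read as 2 standard deviations of a count, so the implied number of fragments is 4 times the square of FPKM over that distance. Of 215412 values above 0, 85.8% gave a whole number within 0.02, or within 3e-06 times the count to the power 1.5 where that was wider because values carry 6 digits. In genes without introns the locus span equals the length used in FPKM, which gave the number of fragments by which each column had been divided. The implied lengths were whole multiples of 3 for 99.9% of 35602 genes, which are 90.2% of all genes, so these are coding lengths without UTRs. Of the numbers in the gene IDs, which ran from 96 to 45937, 6361 had no row in the table analysed, and whether those genes share a property such as the lack of introns is not known. A gene was called intronless where its implied coding length was within 0.2% of its locus span. Both tolerances were set after the values were seen. Fragments in UTRs fell outside these gene models, and PCR copies were not marked by molecular identifiers, so intervals and floors cover counting error only.

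A gene was called detected at an FPKM of 1 or more. It was called tissue-enriched where log2(FPKM + 1) in its highest tissue exceeded that in the next tissue by 2 or more (4-fold), with a highest FPKM of 1 or more. Folds on this scale understate the change of genes with low values. The tissue specificity index tau was computed on log2(FPKM + 1), and 0.85 was the threshold. Pairs of tissues were compared with the same 4-fold limit, and Spearman's rho was computed across genes for all 21 pairs, with an interval from 100 resamplings of the genes against which other settings were judged. Adjacent genes enriched in the same tissue were counted and set against 10000 random placements of the enriched genes among genes with an FPKM of 1 or more in any tissue. With 1 library per tissue there is no replicate check, no p-value was computed, and differences are between these libraries.

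The named IDs followed a rule written before the data were examined. They are the 2 IDs with the largest increase and the 2 with the largest decrease in each comparison, and the 2 enriched IDs with the largest fold over the next tissue, all with a highest FPKM of 10 or more. The alternatives fixed at the same time were other detection thresholds, pseudocounts of 0.1 and 0.5, other filters, a 2-fold limit, rescaling to equal upper quartiles or by trimmed means (30% of log ratios and 5% of abundances trimmed from each end), non-overlapping intervals, and single tissues left out. Rescaling to the fragments in gene models, rescaling to equal sums of FPKM, leaving out intronless genes, leaving out overlapping neighbours and a minimum of 10 fragments were added after the data were examined. The steps were tested on simulated counts for 37475 genes with 200 genes changed. With no change simulated, counting error alone gave 0 tissue-enriched genes and 0 genes in each pairwise comparison except 1 gene for silique against flower. Of 100 genes changed 8-fold, 97 were recovered as tissue-enriched, as were 100 of 100 changed 16-fold. The changed genes all had a mean FPKM of 1 or more, where changes of this size pass the 4-fold limit unless counting error intervenes. Lower levels and changes near 4-fold were not tried, so recovery there is not known. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.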

Results

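Transcript levels were measured by RNA-seq in 7 tissues of Brassica oleracea, a vegetable species that includes cabbage. The reproductive series was flower bud of 0.8 cm length, flowers open on the same day, and silique, the seed pod, 15 days after pollination. Leaf, stem and root came from plants of 7 weeks. Callus, a mass of cells that divides in culture, was the remaining tissue. Each tissue was 1 library, so no difference has a replicate check. The deposited intervals implied 10446422 fragments in gene models for bud, 8480189 for callus, 8459141 for flower, 10595077 for leaf, 10598033 for root, 9880774 for silique and 8809332 for stem. These were between 61.2% (flower) and 77.5% (root) of the fragments by which FPKM had been divided. The median value above 0 rested on 47.0 fragments in root and on 81.0 in leaf, the lowest and highest of the 7 tissues, and 1 fragment corresponded to a median of about 0.0704 FPKM in root and 0.0801 FPKM in callus.

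Most detected genes were active in many tissues. Of 39481 genes, 30945 reached an FPKM of 1 in at least 1 tissue, and 16005 of these (51.7%) did so in all 7. Another 3564 genes (11.5%) were detected in a single tissue, among them 879 in silique, 837 in bud, 792 in callus, 419 in leaf, 321 in root, 175 in flower and 141 in stem. Callus and bud had the most detected genes, with 25115 and 24935, followed by silique (23937), leaf (23121), flower (22808), stem (22108) and root (20800). The 100 most abundant genes took 11.7% of the summed FPKM in callus and 17.4% in bud, against 20.2% to 21.4% in the other 5 tissues. Over the 10 most abundant genes callus again had the lowest share (3.42%), but root (4.84%) lay below bud (4.93%). The alternatives tried, thresholds of 0.5 and 2 FPKM among them, left every detection count within 1.5 times of the counts above. That limit is wider than the differences between tissues and does not bear on their order. Bud passed callus after upper quartile rescaling (24749 against 24363) and at 10 or more fragments (25354 against 25053). Flower passed leaf at 0.5 FPKM (25478 against 25080), after upper quartile rescaling (23235 against 22895) and at 10 or more fragments (23567 against 23367). Root had the fewest throughout.

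The reproductive organs and callus held most of the tissue-enriched genes. In total 2212 genes (7.15% of those detected) were at least 4-fold higher in 1 tissue than in each of the others. Bud had 565 and silique 559 on the deposited scaling, followed by callus with 381, root with 312, flower with 195, leaf with 149 and stem with 51. This order rested on the scaling, because after trimmed mean rescaling root had the most (589), ahead of silique (526) and bud (524). Genes enriched on the deposited scaling reached higher levels in root and flower (median 70.9 and 68.6 FPKM) than in bud (20.1 FPKM) or silique (13.7 FPKM). No median was computed for the sets after rescaling. In silique, 114 of 525 enriched genes with an implied coding length were intronless (21.7%, 95% Wilson interval 18.4% to 25.4%). In bud 0 of 554 were, with an upper Wilson bound of 0.689%. The share was 8.92% in callus and 6.43% in root, and 2.58% (783 of 30369) over all detected genes with a coding length. Wilson bounds here and below treat genes as independent draws and take no account of genes without a row. Among genes with an implied coding length, which needs fragments in some tissue, intronless genes were 26.8% of those listed at 0 in bud. They were 14.7% (root) to 22.4% (flower) of those listed at 0 in the other tissues, and 5.29% of all genes with a coding length. Whether rows of intronless genes expressed in bud were lost before the table was analysed is not known. Such a loss would bias the contrast of bud with silique and their numbers of enriched genes, and could bias the counts of other tissues. All of these hold for the analysed rows alone. Without intronless genes, an alternative chosen after the data were seen, silique kept 445 of its 559 genes and bud all 565. The counts also depended on which tissues had to be exceeded: without bud, flower had 769 enriched genes and leaf 265, without flower, bud had 1106, and without callus, root had 804.

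**Figure D1:**
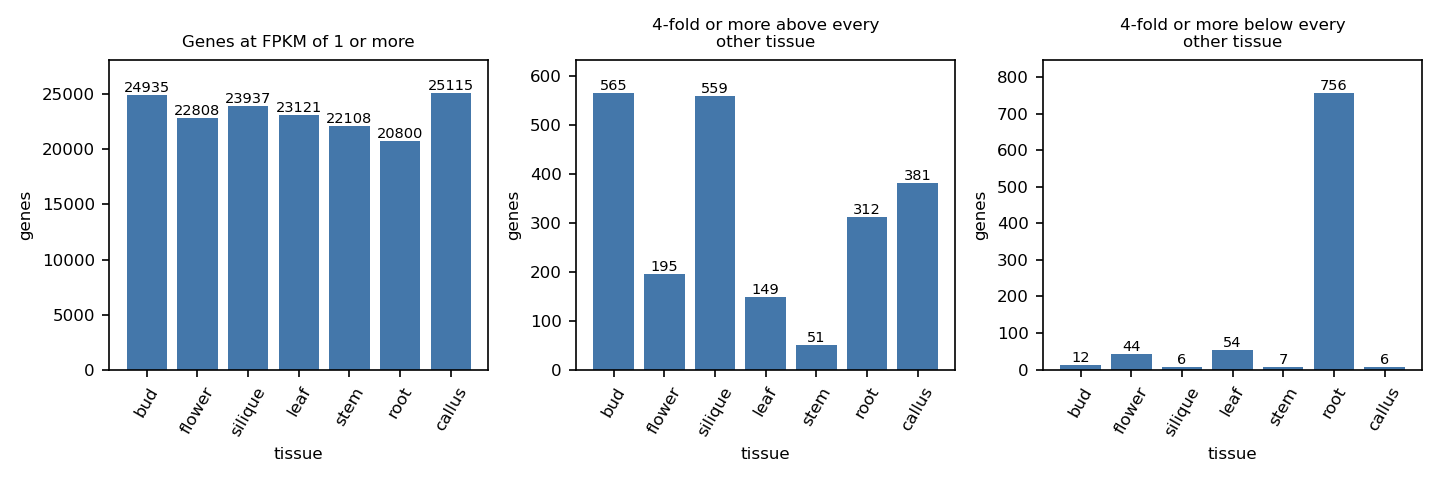
Bars give, for each of the 7 tissues (1 library each), the number of genes at an FPKM of 1 or more (left), at least 4-fold above every other tissue (centre) and at least 4-fold below every other tissue (right). On this deposited scaling bud (565) and silique (559) lead the centre panel, and root (756) stands apart in the right panel.

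Some enriched genes were abundant in 1 tissue and near or at 0 elsewhere. In bud, Bol043888 (Scaffold000004, 3319169 to 3321616) was at 2057 FPKM (deposited interval 2034 to 2079.8) and at 1.05 FPKM (0.542 to 1.56) in flower, the next tissue, a log2 difference of 9.97. Bol033811 (Scaffold000041, 1858244 to 1858840) was at 1109.9 FPKM in bud and at no more than 0.609 FPKM elsewhere. In silique, Bol023115 (Scaffold000102, 662977 to 663303) was at 414 FPKM (392 to 437) and was listed at 0 in the other 6 tissues, where 3 fragments would have been 0.939 to 1.05 FPKM. Bol004744 (Scaffold000316, 332592 to 334645) was at 1184 FPKM in silique and 1.99 FPKM in stem, a log2 difference of 8.63. In flower, Bol005087 (Scaffold000308, 250768 to 251447) was at 611 FPKM against 7.05 FPKM in bud, and Bol001117 (Scaffold000467, 45715 to 46201) at 106 FPKM against 0.771 FPKM in silique.

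In root, Bol013448 (Scaffold000187, 1066190 to 1067683) was at 408 FPKM (399 to 417) and Bol024137 (Scaffold000094, 243997 to 245686) at 352 FPKM. Callus was the next tissue for both, at 2.72 and 4.76 FPKM, with log2 differences of 6.78 and 5.94. In callus, Bol032338 (Scaffold000049, 1233461 to 1234814) was at 81.2 FPKM against 0.157 FPKM in leaf, and Bol008858 (Scaffold000242, 608927 to 609700) was at 283 FPKM against 3.64 FPKM in silique. In leaf, Bol021617 (Scaffold000114, 389656 to 390192) was at 214 FPKM against 6.15 FPKM in flower and Bol005954 (Scaffold000289, 510148 to 510739) at 78.9 FPKM against 2.76 FPKM in bud. Stem had the smallest leading folds. Bol043384 (Scaffold000004, 172823 to 174779) was at 30.4 FPKM there against 1.46 FPKM in flower, and Bol025257 (Scaffold000088, 346033 to 346466) at 30.1 FPKM against 2.28 FPKM in silique. Counts of enriched genes moved with the scaling of the columns. Trimmed mean rescaling shifted callus by -0.42, leaf by -0.19, bud by -0.12, silique by -0.11, flower by 0.22, stem by 0.22 and root by 0.39 on the log2 scale, and gave 589 genes in root, 526 in silique, 524 in bud, 295 in flower, 217 in callus and 83 in stem. Per fragment in gene models, the count in root moved the other way, to 254.

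**Figure D2:**
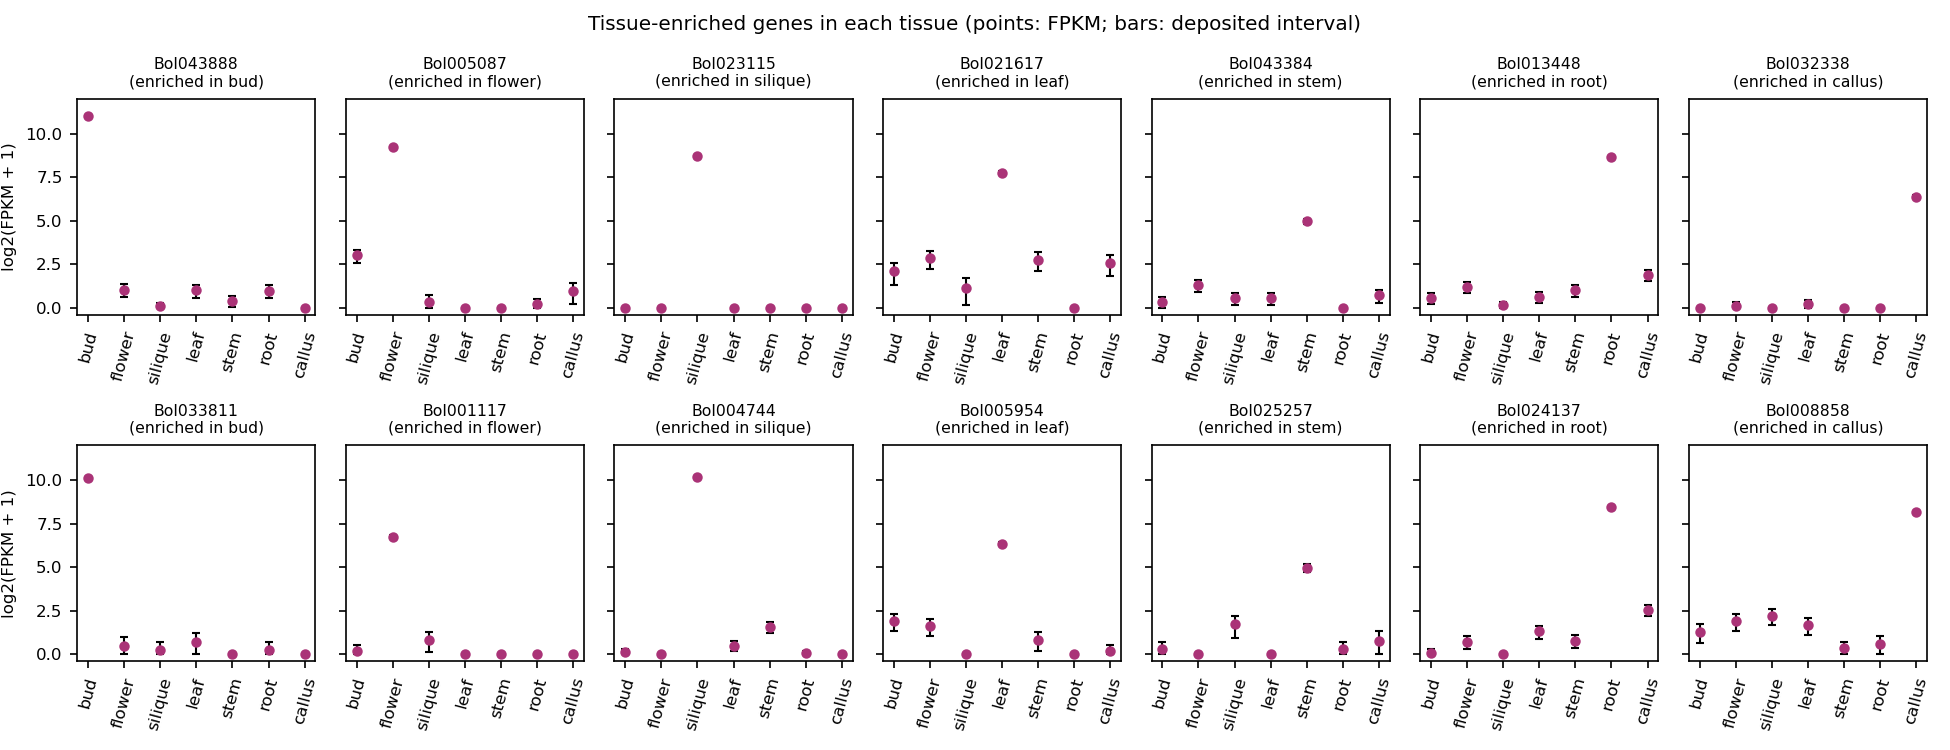
Points give log2(FPKM + 1) in each tissue for 14 tissue-enriched genes, 2 per tissue, and bars the deposited interval, which covers counting error only. Each gene has 1 high tissue, from 30.1 FPKM for Bol025257 in stem to 2057 FPKM for Bol043888 in bud.

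The tissue specificity index tau, on the deposited scaling, was also highest most often in bud and silique. It was 0.85 or more for 3278 genes (10.6% of those detected), and the median over all detected genes was 0.386. Bud was the highest tissue for 1020 of these genes, silique for 849, callus for 563, root for 305, flower for 291, leaf for 184 and stem for 66. Bud and flower were often paired, as were root and callus. Among genes with a single next tissue, flower was next for 544 of 890 bud genes (61.1%), bud for 214 of 283 flower genes (75.6%), callus for 203 of 287 root genes (70.7%) and root for 240 of 530 callus genes (45.3%). Silique genes were next highest in stem (176 of 589) or bud (171). The count depended on the settings, from 1560 for genes reaching an FPKM of 5 to 7026 with no filter on low values.

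Root had the most distinct profile. Across the 30945 detected genes, root had the lowest Spearman's rho with bud (0.545) and flower (0.545), and its mean over the other 6 tissues was 0.633, against 0.699 to 0.761 for the other tissues. Its closest tissue was callus (0.766). The highest values were for silique and stem (0.817), bud and flower (0.800) and leaf and stem (0.786). Genes are not independent replicates, so these values describe the 7 libraries. The highest pair changed with the genes used. It was bud and flower (0.872) over all genes and bud and silique (0.841) over genes detected in every tissue, while root had the lowest mean of the 7 tissues in both cases.

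**Figure D3:**
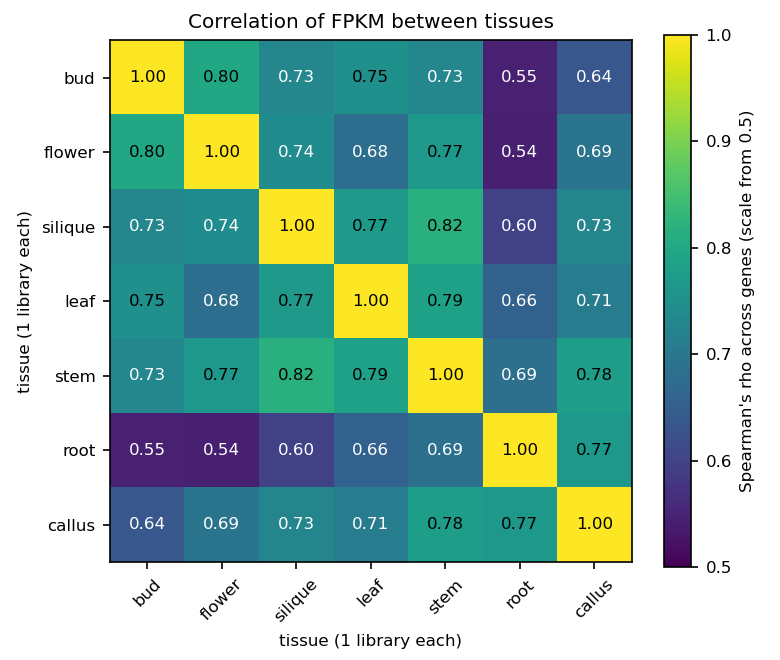
Cells give Spearman's rho across 30945 genes for each pair of the 7 tissues (1 library each), on a colour scale that starts at 0.5. Root has the lowest values, 0.545 with bud and with flower, and silique with stem the highest, 0.817.

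Leaf, root and stem of the same age differed most between leaf and root. Of 25529 genes compared, 3500 were at least 4-fold higher in leaf and 2205 at least 4-fold higher in root. The largest increases in leaf were Bol020349 (Scaffold000123, 416098 to 418252), at 778 FPKM against 0.139 FPKM in root, and Bol030013 (Scaffold000062, 427494 to 428142), at 1023 FPKM against 0.738 FPKM. Their log2 differences were 9.42 (9.16 to 9.63 from the interval bounds) and 9.20 (8.58 to 10.04), with 2 and 3 fragments behind the root values. In root, Bol035837 (Scaffold000032, 2011797 to 2013553) was at 2096 FPKM against 1.09 FPKM in leaf, and Bol028063 (Scaffold000074, 1491232 to 1491888) at 1452 FPKM against 0.575 FPKM, with log2 differences of 9.97 and 9.85. The balance of directions rested on the scaling. The share higher in leaf was 61.3% as deposited, 51.3% after upper quartile rescaling and 45.7% after trimmed mean rescaling, which turned the direction. All pairwise counts rose by more than 1.5 times with a pseudocount of 0.1 or a 2-fold limit.

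Between leaf and stem, 1495 of 25225 genes were at least 4-fold higher in leaf and 1927 in stem. Bol003395 (Scaffold000351, 67542 to 68506) was at 4002 FPKM in leaf and 1.28 FPKM in stem, a log2 difference of 10.78 (10.30 to 11.47). Bol038487 (Scaffold000020_P1, 55911 to 57532) was at 590.0 FPKM in leaf and 0.442 FPKM in stem. In stem, Bol004773 (Scaffold000315, 451146 to 452747) was at 1051 FPKM against 0.0760 FPKM in leaf, where 1 fragment was implied, and Bol015488 (Scaffold000164, 210824 to 211414) at 1052 FPKM against 0.218 FPKM, also 1 fragment. Bol015488 was higher still in silique (3260.0 FPKM). The share higher in leaf was 43.7% as deposited and 28.1% after trimmed mean rescaling. It was 52.5% with a pseudocount of 0.1, which enlarges folds of low values. At 2-fold it was 60.7%, on the deposited scaling, where the median gene was 0.35 higher in leaf than in stem on the log2 scale.

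Between root and stem, 1621 of 24731 genes were at least 4-fold higher in root and 2976 in stem. Bol029238 (Scaffold000067, 1228318 to 1234274) was at 765 FPKM in root and 0.0680 FPKM in stem, a log2 difference of 9.49 (9.38 to 9.59). Bol003395, which also led leaf over stem, was at 654 FPKM in root. In stem, Bol040169 (Scaffold000014, 754017 to 754986) was the most abundant gene of that library, at 9211 FPKM (9141 to 9281) against 2.37 FPKM in root, a log2 difference of 11.42. Bol005359 (Scaffold000301, 309781 to 310746) was at 2560 FPKM (2523 to 2597) in stem and 0.268 FPKM in root. More genes were higher in stem under every scaling tried.

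From bud to open flower, more genes fell than rose. Of 26226 genes compared, 2175 were at least 4-fold lower in flower and 943 at least 4-fold higher. Bol043888 and Bol033811, which led the bud-enriched genes, had the largest decreases, with log2 differences of 9.97 and 9.63 between bud and flower. Bol012996 (Scaffold000191, 414286 to 415939) was at 2289 FPKM in flower (2263 to 2315) and 21.5 FPKM in bud (18.9 to 24.0), a log2 difference of 6.67. Bol044575 (Scaffold000002, 3848104 to 3849246) was at 246 FPKM in flower and 1.57 FPKM in bud. The share higher in flower was 30.2% as deposited, 45.1% after trimmed mean rescaling and 44.3% per fragment in gene models.

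From flower to silique, 1722 of 26179 genes were at least 4-fold higher and 1554 at least 4-fold lower. Bol004744, the silique-enriched gene above, was listed at 0 in flower, where 3 fragments would have been 0.155 FPKM. Bol028592 (Scaffold000070, 662386 to 663518) was at 549 FPKM in silique (533 to 566) and also listed at 0 in flower. Bol045054 (Scaffold000001_P2, 2212896 to 2215032) was at 1351 FPKM in flower and 0.0830 FPKM in silique, a log2 difference of 10.29 (10.12 to 10.42), and Bol032457 (Scaffold000049, 2000533 to 2000905) was at 795 FPKM in flower, 1485 FPKM in bud and listed at 0 in silique. In flower, 483 genes were at least 4-fold higher than in both bud and silique, and 462 at least 4-fold lower than in both. Another 18 genes were higher at each step and 65 lower at each step. Independent lists would share 59.8, 76.9, 43.5 and 106 genes in the order given. Both steps use the same flower library, which these values leave out, so the counts do not measure how many changes were reversed between stages. The share higher in silique was 52.6% as deposited and 41.6% after trimmed mean rescaling, and it also lay below 50% after upper quartile rescaling (47.4%) and per fragment in gene models (45.5%).

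Callus, the cultured tissue, was compared with all 6 organs. Of 30945 genes, 381 were at least 4-fold higher in callus than in every organ, and 6 were at least 4-fold lower. An excess of higher genes was not particular to callus. By the same criterion bud had 565 higher and 12 lower, silique 559 and 6, flower 195 and 44, leaf 149 and 54, and stem 51 and 7. Root had 312 higher and 756 lower, or 589 and 579 after trimmed mean rescaling. Among the lower genes, Bol019016 (Scaffold000134, 1100441 to 1102235) was at 0.141 FPKM in callus, on 2 fragments, and at 5.80 FPKM in root, the lowest organ, a log2 difference of 2.58. Bol006042 (Scaffold000286, 115687 to 118380) was at 1.29 FPKM in callus and 12.2 FPKM in flower, its lowest organ, a log2 difference of 2.53. The 2 leading genes in the upward direction were Bol032338 and Bol008858, as given for the enriched genes. Trimmed mean rescaling gave 217 higher and 17 lower genes.

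Genes enriched in the same tissue lay next to each other more often than after random placement. Of 38782 adjacent pairs, 133 were enriched in the same tissue, against a mean of 24.0 and a range of 8 to 42 over 10000 placements. Adjacent means next to each other among the analysed rows, so a gene without a row may lie between them. Silique had 43 such pairs, bud 39, callus 27, root 9, flower 8, leaf 6 and stem 1. The mean after random placement was 7.99 for silique, 8.16 for bud, 3.76 for callus and 2.54 for root, where the highest of 1000 placements (11) exceeded the 9 observed pairs. For stem the highest placement also gave 1 pair. Without pairs whose loci overlap, 114 remained.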

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

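The settings that rescaled to the fragments in gene models or to equal sums, left out intronless genes or overlapping neighbours, or required 10 fragments were chosen after the data were seen, as were all settings for the genes shared by pairs of tissues or low in 1 tissue. The others were set beforehand. No paired analysis was possible because each tissue has 1 library and no result comes from a test. Of the values that answer a comparison, 154 stayed within 1.5 times of the reported count, or within the resampling interval of a correlation, under the setting tried and 45 moved; among the other values 155 stayed and 139 moved. There, a log2 ratio of a named gene counted as moved where its shift exceeded the wider side of its range from deposited interval bounds. No such ratio changed sign, but these genes were chosen for their large folds, so this says nothing about stability. The share of summed FPKM in the 10 instead of the 100 highest genes always counted as moved. All detection counts stayed within 1.5 times, a limit wider than the differences between tissues. Dropping the filter on low values moved no enriched or pairwise count, because a 4-fold change with a pseudocount of 1 already needs a higher value. Requiring intervals not to overlap moved none of them either, and these intervals cover counting error only. Neither setting says anything about stability between libraries. Their unmoved values, like the detection counts, are nevertheless among the 154 that stayed, so that number overstates stability. The gene list alternatives gave no value, since 0 IDs matched, nor did those on quantification status, since no status was among the columns used. Depth limited the low values: 1 fragment was 0.0704 FPKM at the median gene in root and 0.0801 FPKM in callus.

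At 2-fold, which admits more genes by construction, enriched genes numbered 1200 in bud, 1463 in callus, 824 in flower, 904 in leaf, 1079 in root, 1059 in silique and 369 in stem. Pairwise counts at 2-fold were 13708 for leaf against root, 10960 for leaf against stem, 11649 for root against stem, 9940 for flower against bud, 10155 for silique against flower and 1530 for callus, and 495 adjacent pairs were enriched in the same tissue. Up to 3 genes apart, 245 pairs were. With a pseudocount of 0.1, which enlarges folds of low values, enriched genes numbered 864 in bud, 688 in callus, 295 in leaf, 866 in silique and 96 in stem, and pairwise counts were 9306 (leaf against root), 6272 (leaf against stem), 7615 (root against stem), 5345 (flower against bud), 5729 (silique against flower) and 728 (callus). Genes with tau of 0.85 or more numbered 2019 with that pseudocount, 6434 on linear FPKM, 7026 with no filter and 1560 above an FPKM of 5. With bud left out, flower had 769 enriched genes and leaf 265; without flower, bud had 1106; without callus, root had 804, as fewer tissues had to be exceeded. Trimmed mean rescaling gave 217 enriched genes in callus, 295 in flower, 589 in root and 83 in stem, and 234 genes for callus against all organs; upper quartile rescaling gave 499 in root. The cause was not tested beyond the shift of the columns. The correlation of flower with root was 0.523 as Pearson's r of log2 values, 0.695 over all genes and 0.511 over genes detected in every tissue, and that of silique with stem was 0.829 and 0.869 in the first and second of these; the cause was not tested.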

Other observations

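The counts of genes shared by pairs of tissues, of genes low in 1 tissue and of runs of neighbours, and the tests of root depth, of neighbouring root-low genes and of RNA carried between callus and root, were chosen after the results were seen; the tests of rescaled counts, of genes at 0 in root, of overlapping loci and of equal fragment numbers were set before theirs were. Some genes marked a pair of tissues. Bud and flower shared 466 genes at least 4-fold higher in both than in each of the other 5 tissues, and callus and root shared 263. The next pair, root and stem, shared 33, and flower and leaf shared 0. With a pseudocount of 0.1, bud and flower shared 844 and callus and root 572, and the next pair was bud and silique (104). Genes could also be low in a single tissue. Root had 756 genes at least 4-fold lower than in each of the other 6 tissues, leaf 54, flower 44, bud 12, stem 7, callus 6 and silique 6. With a pseudocount of 0.1 these were 1913, 335, 210, 64, 122, 40 and 74, in the same order of tissues. Trimmed mean rescaling gave 579 in root, 72 in leaf, 24 in flower and 17 in callus, and root had the most under every setting tried. Of the genes listed at 0 in 1 tissue and at 10 FPKM or more in the other 6, all 36 were at 0 in root.

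Neighbouring enriched genes, next to each other among the analysed rows, formed 16 runs of 3 or more genes, 56 genes in all. The longest, chosen after their values were seen, held 5 genes each. One, enriched in silique, ran from Bol045090 to Bol045094 (Scaffold000001_P2, 3159618 to 3174930), with highest values of 3.97 to 152 FPKM. The other, enriched in bud, ran from Bol043886 to Bol043890 (Scaffold000004, 3312657 to 3328892), with 37.5 to 2057 FPKM, and holds Bol043888.

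Intronless genes were unevenly spread over the tissues, which was noticed while coding lengths were being checked. They were 1882 of 35602 genes with an implied coding length (5.29%), and 783 of the 30369 detected ones (2.58%). Among genes at 5 FPKM or more they were 8 of 15719 in bud (0.0509%, 95% Wilson interval from 0.0258% to 0.1004%), 20 of 13772 in flower (0.145%), 29 of 14968 in leaf (0.194%) and 55 of 13502 in stem (0.407%). The counts were 122 of 15206 in silique (0.802%), 138 of 16851 in callus (0.819%) and 120 of 12280 in root (0.977%). Of the genes at 5 FPKM or more in silique, 85.4% of those with introns and 5.74% of the intronless ones also reached 5 FPKM in bud. Among genes with a coding length that were listed at 0 in bud, 1100 of 4097 were intronless (26.8%), against 14.7% to 22.4% in the other tissues. A coding length needs fragments in some tissue, so genes at 0 throughout are left out. The numbers in the IDs ran from 96 to 45937, and 6361 numbers in that span had no row in the table analysed. Whether rows were lost or left out in a way tied to expression in bud is not known. If they were, all counts that set bud against other tissues are biased. Intronless shares at 5 FPKM or more lay below 2.58% in every tissue. The share also differed between all genes and detected genes, so these low shares do not tell whether rows were lost. The missing genes could be expressed in other tissues too. Detection counts, numbers of tissues per gene, correlations and the intronless shares could then be biased in every tissue. All of these hold for the analysed genes alone.

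The 756 root-low genes had a median of 0.514 FPKM in root and 24.8 to 47.6 FPKM in the other tissues. Lower depth of the library as a whole was argued against by the 10598033 implied fragments in root, above the median of 9345053 in the other tissues. The median value above 0 nevertheless rested on the fewest fragments in root (47.0), so this total does not speak for single genes. Scaling left the excess in place, with 579 root-low genes after trimmed mean rescaling and at most 72 genes low in any other tissue. Missing genome segments of several genes would place root-low genes together. Of the root-low genes, 8.60% had a root-low gene as the next detected gene, so most did not lie together. No such share was computed for random placements. The 28 adjacent pairs exceeded both the mean (14.6) and the highest (26) of 1000 placements, so such segments stay open for those genes. Genome segments or genes missing in the root plants cannot be told apart from low expression for the 15.3% listed at 0 in root, because the plants' genomes were not measured, and 300 of the 756 had 10 or more fragments in root.

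The 133 adjacent pairs enriched in the same tissue could arise from shared reads. Overlapping gene models were argued against by the 114 pairs left without overlapping loci, above the highest of 1000 placements (40). Full counting of the same reads at neighbours alike over their whole length would give equal fragment numbers. Only 4.51% of the pairs lay within 10% of each other, and the median ratio was 3.02. Neighbours of unlike length, or alike in part, could differ in fragments under full counting, so these values do not bear on them. Reads divided unequally between duplicated neighbours were not tested and stay open, as does joint regulation by tissue.

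The 263 genes high in both callus and root might reflect RNA of one tissue in the other library. Among genes at 100 FPKM or more in root, the 5th percentile of the callus to root ratio was 0.0678, and the median ratio of the shared genes (0.857) was 12.6 times that; in the other direction the median was 653 times the 5th percentile. Rescaling by trimmed means left 229 shared genes against 87 for root and stem, the next pair apart from bud and flower. These values argue against carried RNA and column scaling as the whole cause. A hypothesis left open is that cultured cells and root express a common set of genes, which was found and examined on the same libraries.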
